A study of Setaria viridis with 13 samples.

How the data were processed

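RNA was sequenced from 13 tissue and stage samples of wild-type Setaria viridis grown in hydroponics, with 3 biological replicates behind each sample. Per the labels' protocols, the replicates were grown at different times and sequenced separately, and per the series text some were sequenced more than once. Per the labels' protocols, polyadenylated RNA was turned into cDNA with the SMARTer kit, made into Illumina libraries and read as paired-end reads of 100 nt on a HiSeq2000. The cDNA chemistry and the read length were the same for all samples in the labels. Per the submitters' processing notes the authors' tools included STAR and DESeq2, with no role or version. The genome build, the annotation and how the replicates were merged are not given in the sources used here.

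The deposited expression table holds log2 values per annotated transcript, 1 column per sample, rounded by the authors to 2 decimals. Its values run from 0 to 16.6. Taken as log2(FPKM + 1) they give back FPKM (fragments per kilobase of transcript, scaled to the total of each sample) that sum to 884742 to 1110010 per sample over all transcripts, while natural logs would give sums of 1.51e+07 to 3.85e+07. The base of 2 and the added 1 were inferred from the values and are not stated in the labels. FPKM has no fixed sum, and the sums alone do not settle the added 1. The deposited table of start site offsets holds 1 signed whole number of nt per gene for 4900 genes, all of them in the expression table. How the offsets were made and their sign convention are not given in the sources used here.

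FPKM divides by gene length and by the total of each sample, so a few very abundant genes in a sample lower the values of all others there. Rounding to 2 decimals limits the precision of genes near 0. A value of exactly 0 can be a failed estimate and is reported as listed at 0, with no fold against it. The values carry no read counts, so the depth of each sample and the counting error of each value are unknown. With merged replicates there is no spread between replicates, and intervals and p-values are given only for statistics across genes of the offsets.

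All computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9. The table holds 40599 transcripts of 35471 genes, of which 31939 have 1 transcript and 3532 have more. The transcript with the highest mean FPKM stood for the gene. In genes with more than 1 transcript the median gap to the top transcript was 0.015 log2. This counted the top transcript against itself and so understates the gap between transcripts. At 0 in all samples were 948 genes. After this step the FPKM of genes summed to 629781 in the lower leaf section, the lowest, and 823911 in the root, the highest. None of the gene IDs matched the 34587 genes of the reference gene table (assembly Setaria_viridis_v4.0), so 25 gene lists fixed beforehand could not be used and no coordinates are given.

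Each sample was its own group, by its title. The 10 comparisons of 2 samples were the leaf 3 tip against 3 other leaf parts, the 2 meristems, the vegetative meristem and the coleoptile each against the V3 bulk shoot, the 2 panicles, root against shoot, and the V5 and R bulk shoots against V3. A gene was called higher or lower when its log2(FPKM + 1) differed by at least 2 and the higher sample had an FPKM of at least 5. The pseudocount of 1 understates differences of low genes. The rule was run on simulated data made from the V5 bulk shoot profile, with 200 changed genes among 35471 and noise of SD 0.2 on the log2 scale. The changed genes were drawn only from those at FPKM 5 or more in that profile and were then raised. The rule found 0% of changes of 2-fold, 39.5% of 4-fold and 100% of 8-fold, with 0 unchanged genes called. These shares do not hold for genes of lower FPKM, which the FPKM minimum and the pseudocount can hide. The noise was set by choice and held no counting error. The 0 unchanged genes called follow from that setting and give no rate of false calls for the real samples. The genes named are at most 2 higher and 2 lower per comparison, those with the largest log2 difference past the rule, at most 2 per sample by FPKM among sample-specific genes, and the lowest coefficients of variation among constant genes. Genes named under other rules are said to be so.

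Similarity was Spearman's correlation over all genes with average-linkage clustering. The tau index used log2(FPKM + 1), with at least 0.85 and an FPKM of at least 5 in the highest sample, and on simulated single-sample genes 94.0% were found. Those genes were set to 0 in all other samples, so only the FPKM minimum could lose them. Constant genes had a coefficient of variation under 0.2 and a mean FPKM of at least 10. To see whether a set of called genes also stood apart in 2 samples not used to call it, its median log2 difference there was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. This describes these samples and is not a test. Some of the samples used in this way were close to those used for calling, such as the V5 to the V3 bulk shoot (Spearman 0.967). Part of such a difference then follows from the choice of genes. Start offsets were tested with a two-sided exact sign test, and their relation to expression with 100000 permutations.

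Alternatives were pseudocounts of 0.1 and 5, no minimum FPKM or a minimum of 20, a log2 difference of at least 1, rescaling by the median ratio to the geometric mean over the 9792 genes at FPKM 1 in all samples, and rescaling to equal sums. The equal sums lay above the sum of every sample, so all values rose and more genes could pass the same pseudocount and FPKM minimum. Leaf tip and base, with nearly equal sums (633949 and 634132), went from 395 genes past the rule to 520 this way. Median-ratio rescaling divided each sample by a factor and so changed levels too. It lowered all values of both meristems (log2 factors of 0.34 and 0.40) and raised those of leaf tip and base (-0.33 and -0.54). Its counts therefore reflect level as well as relative scale. Other alternatives changed the expression threshold, the correlation, the tau and variation settings and the offsets included. Where rescaling shifted a pair by over 0.1 log2, both counts are given. Sequence features of introns near the start, which the series title names, were not analysed here because no genome was used.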

Results

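Gene expression was profiled across the life of green millet (Setaria viridis), a small C4 grass, in 13 tissue and stage samples of 1 wild-type accession. Genes regulated during development and the start sites of transcription are among the subjects that the series title gives. At 3 days after germination the coleoptile, the sheath that covers the emerging shoot, was taken at the stage labelled VE. At 10 days (stage V3) the bulk shoot, the vegetative meristem and 4 parts of leaf 3 were taken. These parts were a lower section under the ligule of leaf 2, a mid section over that ligule, the base over the leaf's own ligule and the tip. At 15 days (V5) the samples were bulk shoots, bulk roots and the inflorescence meristem, and at stage R they were bulk shoots (20 days) and panicles before (22 days) and after (25 days) anthesis. Each sample had 1 column of values with its 3 biological replicates merged, so no difference between samples could be set against replicate error and no test between samples was made. Sequencing depth could not be read from the values and is unknown. Genes are called higher or lower by the size rule, a difference of at least 2 in log2(FPKM + 1) with an FPKM of at least 5 in the higher sample. The files used here do not pair gene IDs with names, and genes are given by ID.

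A median of 15634 genes reached an FPKM of 1 per sample. The base of leaf 3 had the fewest (13845, or 39.03%) and the R bulk shoot the most (17641, or 49.7%). These samples also had the lowest and the highest median-ratio factor (log2 of -0.54 and 0.55). The counts were not made on rescaled values, so the part of scaling in this order is unknown. In all 13 samples 9792 genes (27.6%) reached that level, 13218 genes (37.3%) reached it in none and 2602 genes reached it in 1 sample. The 10 most abundant genes held 24.8% of the summed FPKM in the leaf base, 22.9% in the coleoptile and 22.9% in the leaf tip, against 10.1% in the R bulk shoot and 10.5% in the post-anthesis panicle. In the coleoptile a single gene, Si027120m.g, held 12.6% of the sum with an FPKM of 99333.

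For each of the 12 samples that shared a tissue label with another, the sample most alike across genes carried the same label. The V3 and V5 bulk shoots had the highest Spearman correlation of the 78 pairs (0.967) and the R bulk shoot joined them at a mean of 0.959. The lower and mid sections of leaf 3 joined at 0.953, the 2 panicles at 0.945 and the 2 meristems at 0.944. The coleoptile was nearest to the V3 bulk shoot (0.932). The root, the only sample of its label, was the one farthest from each of the other 12, with correlations from 0.709 with the leaf base to 0.792 with the vegetative meristem. The median over all pairs was 0.899. These correlations run across genes, which are not independent replicates.

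**Figure D1:**
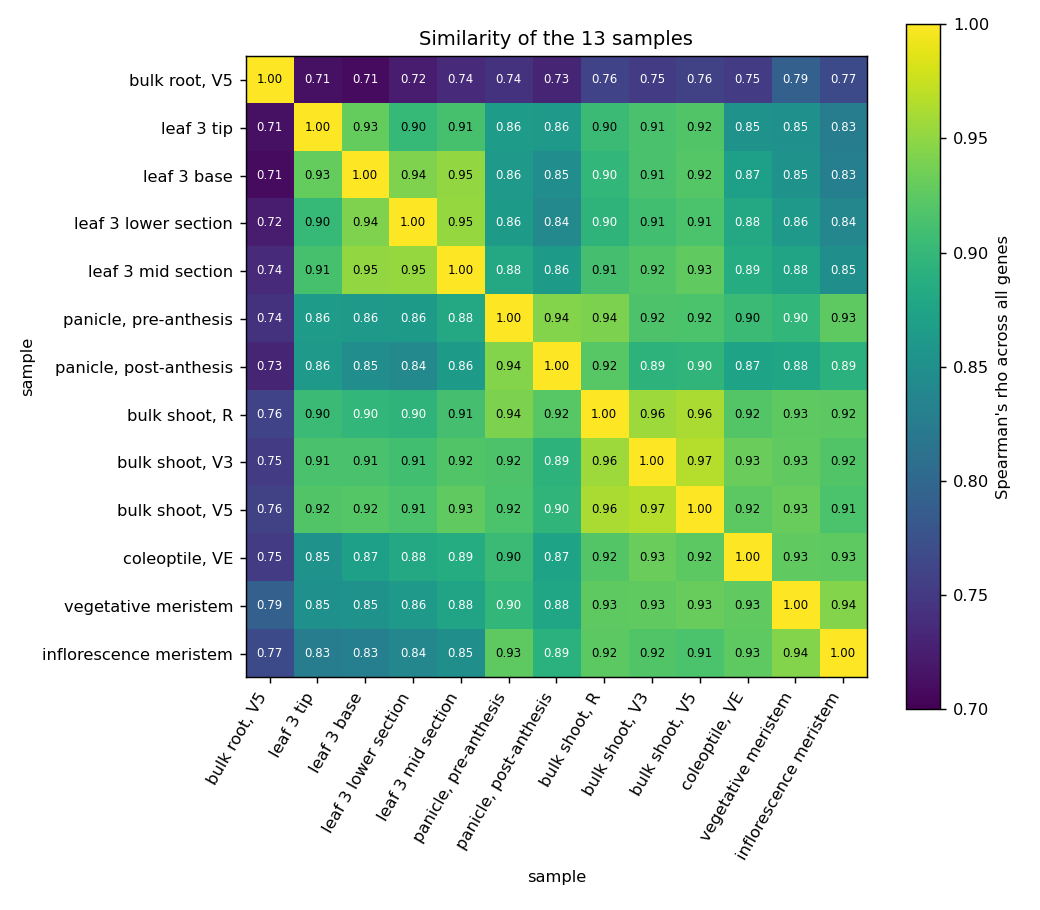
Spearman's rho across all genes for each pair of the 13 samples, with samples on both axes in the order of average-linkage clustering and colour from 0.70 to 1.00. The root differs from every other sample, with values of 0.709 to 0.792, while the 3 bulk shoots reach 0.957 to 0.967 with each other.

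Along leaf 3 the tip stood apart from the mid and lower sections and was closer to the base. Against the lower section 287 genes were higher in the tip and 1021 lower, against the mid section 194 were higher and 924 lower, and against the base 155 were higher and 240 lower. Si005012m.g was at FPKM 1379 in the tip, 1.45 in the mid section and 0.110 in the lower section. Si036679m.g was at 168 in the tip, 0.717 in the lower section and 0.197 in the base, and was higher still in the root (275). Si020642m.g was at 86.4 in the tip, 0.0281 in the mid section and 0.0353 in the base. In the other direction, Si027021m.g was at 0.347 in the tip against 351 in the lower section, 374 in the mid section and 96.7 in the base. Si017684m.g was at 0.257 in the tip against 359 in the lower section and 415 in the mid section, and Si038068m.g was at 0.840 in the tip against 137 in the base.

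The genes higher in the tip than in the lower section were also higher in whole shoots than in the meristem. Their median difference between the V5 bulk shoot and the vegetative meristem, 2 samples outside the leaf comparison, was 1.64 on the log2 scale. The medians of 10000 random lists matched on mean expression ran from -0.20 to 0.37. Genes lower in the tip than in the mid section had a median of -0.22 in the same contrast, just under the lowest random list (-0.21). Genes lower in the tip than in the base were at 0.64 (highest list 0.36), and those lower than in the lower section were at 0.08 (highest list 0.07). With sets and random lists both rescaled, these 3 medians were 0.02 (lowest list 0.04), 0.82 (highest 0.56) and 0.300 (highest 0.303), so the last no longer lay outside its lists. The 3 leaf comparisons share the tip sample, so their gene counts are not independent of each other. Rescaling each sample by the median ratio of widely expressed genes moved the tip by -0.21 against the base, 0.24 against the lower section and 0.25 against the mid section. With it, 150 genes were higher and 347 lower against the base, 395 and 880 against the lower section, and 269 and 796 against the mid section.

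**Figure D2:**
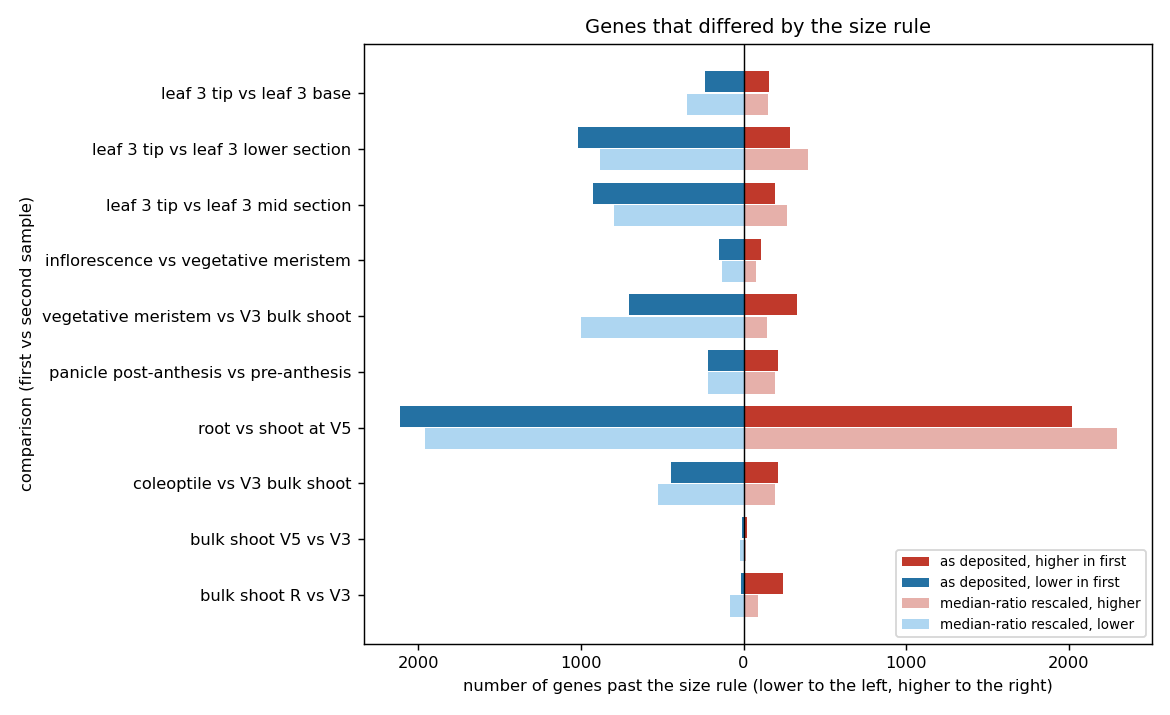
Number of genes past the size rule in each of the 10 comparisons, with genes higher in the first-named sample to the right and lower ones to the left, as deposited (dark) and after median-ratio rescaling (pale). Root against shoot has the most genes (2023 higher, 2115 lower), and the R against V3 bulk shoot comparison goes from 243 higher and 15 lower to 89 and 84 after rescaling.

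Between the 2 meristems, 108 genes were higher in the inflorescence meristem and 149 were lower than in the vegetative meristem. Si038090m.g was at FPKM 65.7 in the inflorescence meristem and 0.320 in the vegetative meristem, and Si030858m.g was at 166 and 2.46. Both had their highest level in the pre-anthesis panicle, at 1977 and 3420. Si030858m.g was also abundant in the V3 and V5 bulk shoots, at 1200 and 1143, where Si038090m.g was at 0.0943 and 0.149. Si007658m.g was at 2.12 in the inflorescence meristem and 62.6 in the vegetative meristem, and Si014780m.g was at 23.4 and 454. In 2 samples that played no part in choosing the genes, the pre-anthesis panicle and the V5 bulk shoot, the higher genes had a median log2 difference of 1.95 (panicle minus shoot), above the highest of the 10000 matched random lists (0.48). The lower genes had a median of -1.45 in that contrast, under the lowest random list (-0.15). Rescaling moved the inflorescence meristem by only -0.06 against the other and left 76 genes higher and 135 lower. It also lowered all values of both meristems, so fewer genes could pass the same pseudocount and FPKM minimum. The balance turned with the threshold, as at a log2 difference of at least 1 there were 1139 higher and 671 lower as deposited. That cut was not run on rescaled values.

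By the size rule, the vegetative meristem had fewer genes above the V3 bulk shoot than below it. As deposited 327 genes were higher in the meristem and 704 lower (31.7% higher). Rescaling moved the meristem by -0.57 against the shoot, after which 147 were higher and 1000 lower (12.8% higher). At a log2 difference of at least 1 the balance was the opposite, with 3189 higher and 1357 lower as deposited. The median difference over all 11100 genes at FPKM 5 in either sample was 0.67 as deposited, so a cut of 1 lies nearer to that shift on the higher side. The cut of 1 was not run on rescaled values, so the part of scaling in this balance is unknown. Si011432m.g was at FPKM 504 in the vegetative meristem and 0.625 in the V3 shoot, and Si011450m.g was at 436 and 0.959. Si030917m.g was at 0.959 in the meristem and 935 in the shoot, and Si003882m.g was at 39.2 and 18305, with its highest level in the leaf base (29327). The 704 lower genes had medians of 5.49 in the V3 shoot, 5.91 in the leaf base and 5.92 in the leaf tip on the log2(FPKM + 1) scale, against 0.91 in the root. At V5 the same genes had a median of -2.78 in the inflorescence meristem relative to the bulk shoot, where the lowest random list was at 0.14. The 327 higher genes had a median of 1.20 in that contrast, against 0.83 in the highest random list. Both V5 samples were close to the V3 samples used for calling (0.944 for the meristems, 0.967 for the shoots). Part of these medians therefore follows from the choice of genes.

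After anthesis 211 genes were higher in the panicle and 220 lower than before it. The 211 higher genes were low elsewhere. Their median log2(FPKM + 1) was 4.32 in the post-anthesis panicle and 1.15 in the pre-anthesis panicle, and from 0.04 (leaf base) to 0.35 (R bulk shoot) in the other 11 samples. Si026461m.g was at FPKM 376 after anthesis and 1.16 before, and Si003352m.g was at 251 and 0.892. The 220 lower genes had medians of 4.56 before anthesis and 1.99 after it. Elsewhere their medians ran from 0.67 in the root, 0.70 in the leaf base and 0.74 in the leaf tip to 3.71 in the R bulk shoot and 3.72 in the inflorescence meristem. Si038090m.g was at 1977 before anthesis and 3.63 after, and Si038106m.g was at 1360 and 22.9. Between the leaf tip and the lower leaf section the higher genes had a median of 0.05, at percentile 75.25 of the random lists, and the lower genes had a median of -0.58, under the lowest random list (-0.26). With sets and random lists both rescaled, the higher genes were at percentile 29.77. The lower genes were then at -0.47, still under the lowest list (-0.07). Rescaling moved the later panicle by -0.04 and gave 191 higher and 217 lower.

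Root and shoot at V5 differed the most of the 10 comparisons, with 2023 genes higher in the root and 2115 lower, together 34.2% of the 12099 genes at FPKM 5 in either. Si023860m.g was at FPKM 11993 in the root and 2.78 in the shoot, and Si027149m.g was at 2319 and 0.141. Si020893m.g was at 0.434 in the root and 1530 in the shoot, and Si037022m.g was at 3.99 and 4972. Both were highest in the leaf tip, at 3590 and 5256. The root-higher genes had a median log2(FPKM + 1) of 4.77 in the root and between 0.77 and 1.73 in the other 12 samples. The root-lower genes had 0.97 in the root and between 3.43 (vegetative meristem) and 4.72 (R bulk shoot) elsewhere. Median-ratio rescaling moved the root by 0.17 against the shoot and gave 2295 higher and 1958 lower (54.0% higher, against 48.9% as deposited). Scaling each sample to the same sum gave 1836 higher and 2920 lower (38.6% higher).

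In the coleoptile 215 genes were higher and 448 lower than in the V3 bulk shoot. Si027120m.g was at FPKM 99333 in the coleoptile and 193 in the shoot, and Si023829m.g was at 1234 and 4.10 and was higher still in the root (2468). Si023761m.g was at 0.705 in the coleoptile and 2368 in the shoot, and Si003564m.g was at 1.11 and 2895. Both of these were highest in the leaf tip. The 448 lower genes were also low in the root, with a median of -3.37 for root minus shoot at V5, under the lowest random list (-0.82). The 215 higher genes had a median of 0.63 in that contrast, above the highest random list (-0.05), with quartiles of -1.56 and 2.86. The V5 shoot was close to the V3 shoot used for calling (0.967), so part of both medians follows from the choice of genes. Rescaling moved the coleoptile by -0.12 against the shoot and gave 196 higher and 525 lower. At a log2 difference of at least 1, 1107 genes were higher and 1030 lower as deposited, a cut not run on rescaled values.

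Bulk shoots of V3 and V5 were nearly alike, with 21 genes higher at V5 and 9 lower. The 21 genes had their highest median log2(FPKM + 1) in the vegetative meristem (3.85), with 3.36 in the V5 shoot, 3.20 in the R shoot and 3.01 in the root, and 0.06 in the leaf tip. Si011432m.g was at FPKM 91.4 at V5 and 0.625 at V3, and Si011450m.g was at 55.5 and 0.959. Both were also named for the vegetative meristem against the same V3 shoot values. Si019730m.g was at 13.8 at V3 and was listed at 0 at V5, and Si004648m.g was at 14.0 and 0.0867. Rescaling moved V5 by -0.29 against V3 and gave 18 higher and 19 lower, which moved the share of higher genes from 70.0% to 48.6%. Scaling to equal sums moved it the other way, with 25 higher and 8 lower (75.8%).

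Bulk shoots of stage R stood further from the V3 shoot than V5 shoots did. As deposited 243 genes were higher at R and 15 lower. Rescaling moved R by -0.78 against V3, the largest shift of the 10 comparisons, and left 89 higher and 84 lower, so that the share of higher genes went from 94.2% to 51.4%. Scaling to equal sums gave 372 higher and 11 lower (97.1%). This scaling also raised all values, which lets more genes pass the rule. Median-ratio rescaling instead lowered the R values (log2 factor 0.55) and raised those of V3 (-0.23) against the same pseudocount and FPKM minimum. The 89 and the 15 passed both as deposited and after median-ratio rescaling. The 243 genes had their highest medians in the panicles, with 4.72 before and 4.47 after anthesis, against 4.20 in the R shoot and 1.43 in the V3 shoot. For 67 of the 243, neither panicle sample was above the R bulk shoot. Si022758m.g was at FPKM 442 at R and 0.141 at V3, with 3901 in the post-anthesis panicle. Si038090m.g was at 321 and 0.0943, with 1977 in the pre-anthesis panicle. Si019730m.g was at 13.8 at V3 and listed at 0 at R, and Si004648m.g was at 14.0 and 0.366. Both were also named for V5 against the same V3 values, in the sample where they were highest. The vegetative meristem, coleoptile, V5 and R comparisons share the V3 bulk shoot column, so their genes and counts are not independent of each other. The median of the 243 genes for pre-anthesis panicle minus V5 shoot was 2.08, above the highest random list (0.25), and that of the 15 lower genes was -2.69, under the lowest (-1.50). The V5 shoot was close to both shoots used for calling (0.967 with V3, 0.961 with R). Part of these medians may therefore follow from the choice of genes.

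**Figure D3:**
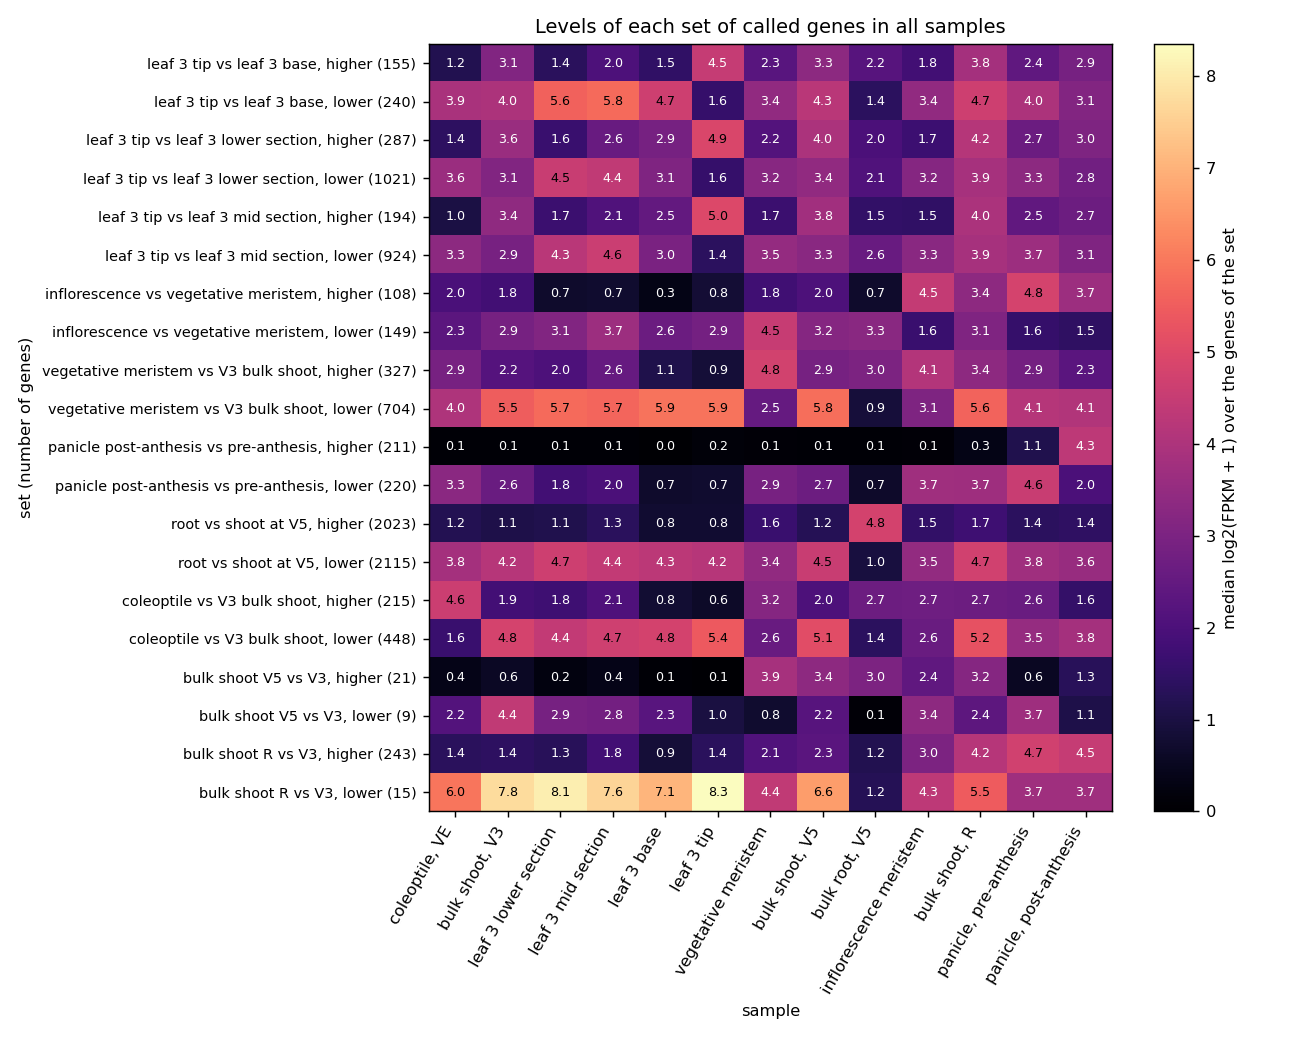
Median log2(FPKM + 1) of each set of genes past the size rule (vertical axis, with the number of genes) in each of the 13 samples (horizontal axis), with colour from 0 upward. Genes higher in the post-anthesis panicle lie at 4.32 there and near 0 outside the panicles, while genes higher in the R bulk shoot are at 4.72 in the pre-anthesis panicle.

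Sample-specific genes were mostly genes of the root and the post-anthesis panicle. By the tau index, which runs from 0 for a gene equal in all samples to 1 for a gene in a single sample, 859 of the 15582 genes at FPKM 5 in any sample (5.51%) reached 0.85. Of these 613 (71.4%) were highest in the root, 166 in the post-anthesis panicle, 36 in the pre-anthesis panicle and 20 in the coleoptile. The 4 parts of leaf 3 together had 14, the 3 bulk shoots 6 and the 2 meristems 4. These low numbers depended on the log scale, since tau on linear FPKM gave 1307 genes in the root, 311 in the post-anthesis panicle, 175 in the inflorescence meristem, 127 in the pre-anthesis panicle and 9 to 63 in each part of leaf 3. In the root, Si023860m.g was at FPKM 11993 with 12.9 in the next sample, and Si036602m.g was at 3168 with 4.24. In the post-anthesis panicle, Si037381m.g was at 643 with 12.3 in the next sample, and Si026461m.g was at 376 with 1.16. In the pre-anthesis panicle, Si037860m.g was at 211 and Si031435m.g at 207, each with the R bulk shoot next (10.96 and 8.78). In the coleoptile, Si016692m.g was at 652 with 6.21 in the next sample. Tissues had unequal numbers of samples, and the root was the only one of its kind. Without the root sample 249 genes reached 0.85, of which 170 were highest in the post-anthesis panicle. With samples averaged by tissue label first, 732 did, of which 586 were highest in the root and 126 in the panicle.

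**Figure D4:**
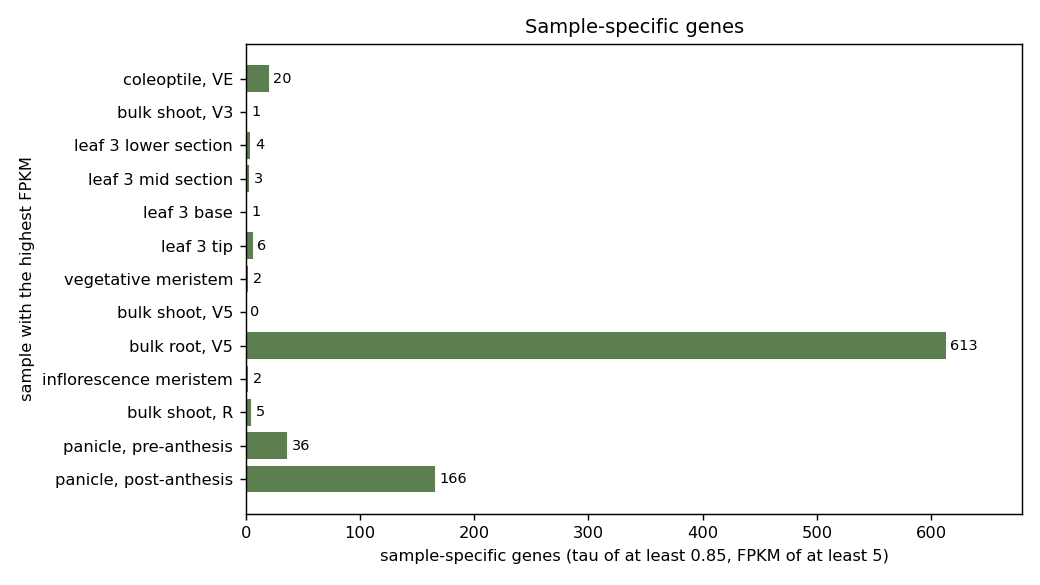
Number of sample-specific genes (tau of at least 0.85 and FPKM of at least 5, horizontal axis) by the sample in which they were highest (vertical axis). The root has 613 and the post-anthesis panicle 166, and no gene was specific to the V5 bulk shoot.

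Few genes held 1 level through development. Of 6683 genes with a mean FPKM of at least 10, 16 had a coefficient of variation under 0.2 over the 13 samples, and the median was 0.59. Si010571m.g had the lowest as deposited (0.149), between FPKM 38.4 and 63.0, followed by Si020398m.g (0.155), between 20.4 and 31.4. This count depended on scaling and, as given further below, on the samples included. After median-ratio rescaling 147 genes were under 0.2, of which 8 were among the 16. Si010571m.g was then at 0.247 and Si020398m.g at 0.164.

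Transcription start offsets, 1 signed number of nt per gene, were listed for 4900 genes (13.8%). The files used here do not state which positions were compared or which was subtracted from which, so no upstream or downstream direction is given. The median was -7 nt with quartiles of -20 and 24, and the range was -200 to 620. No offset lay below -200, 44 lay at or below -180 and 128 lay above 200. Whether offsets were limited on the negative side is not stated in the files used here, and such a limit would lower the negative share. Negative offsets were more common, with 2992 negative, 1825 positive and 83 at 0. Of the nonzero offsets 62.1% were negative (exact 95% interval over genes 60.7 to 63.5, two-sided exact sign test p = 5.95e-64). The interval and the p-value treat genes as independent, which they are not. The share also varied with expression: 79.8% were negative among the 1225 genes of lowest expression and 43.1% among the 1225 of highest. The most common value was -9 nt, in 177 genes, and 36.3% of genes lay between -20 and -1.

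Genes with higher expression had more positive offsets. In 4 groups of 1225 genes, from the lowest to the highest mean log2(FPKM + 1), the median offset was -14, -9, -5 and 4 nt. Spearman's rho between offset and mean expression was 0.33 and Pearson's r was 0.20. The size of the offset without its sign had a rho of -0.11. The permutation p of each rho was 1e-05, two-sided, the smallest that 100000 permutations can give, and 1e-05 for the signed offset after Benjamini-Hochberg adjustment over the 2 relations. These are correlations across genes, which are not independent replicates. Genes with an offset were widely expressed, with 67.1% of them at FPKM 1 in all 13 samples against 21.3% of the other genes.

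**Figure D5:**
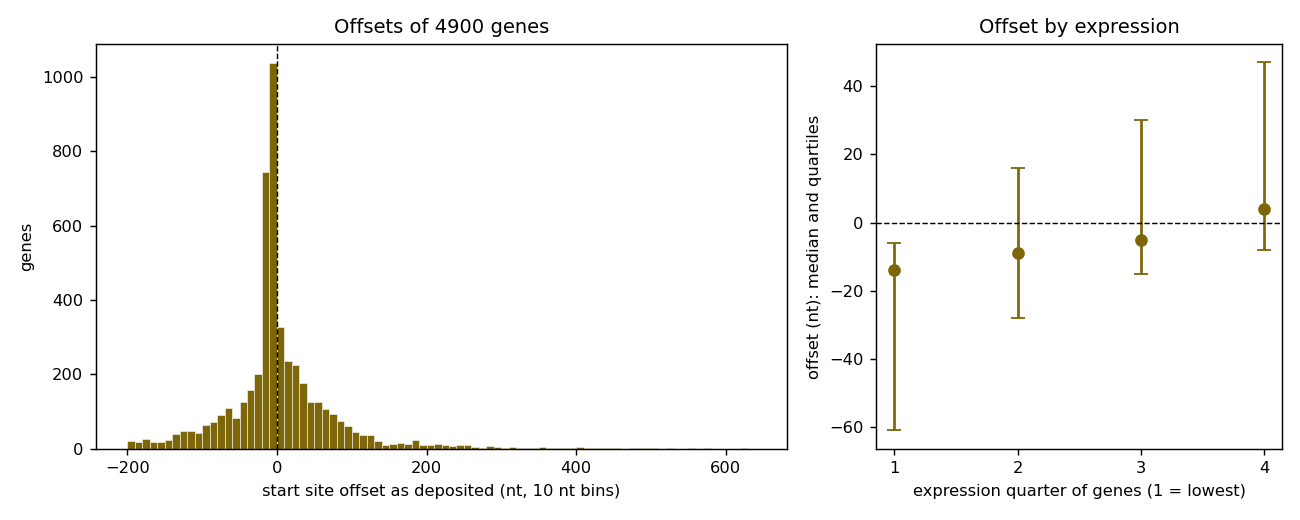
Left, number of genes by deposited start offset in nt, in bins of 10 nt. Right, median offset (points) with quartiles (bars) in 4 groups of 1225 genes by mean expression, from -14 nt in the lowest to 4 nt in the highest.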

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

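Both rescalings were chosen before the data were examined, and the other tests in this part only after the result was seen. The 8 genes named for the V5 against V3 shoots or for the meristems were followed from V3 to V5 in both tissues. With a gene listed at 0 set aside, 1 of them went opposite ways by at least 1 log2 in each of the bulk shoot and the meristem. Si004648m.g was at FPKM 14.0 in the V3 bulk shoot and 0.0867 in the V5 bulk shoot, but at 0.558 in the vegetative meristem (V3) and 9.41 in the inflorescence meristem (V5). Its log2 difference was -3.79 in the shoot and 2.74 in the meristem, which are -6.53 apart. It kept these directions after median-ratio rescaling. Si019730m.g, the gene set aside, also went opposite ways. It was at 13.8 in the V3 bulk shoot and listed at 0 at V5, so no difference is given for it, and was at 0.636 in the vegetative and 2.76 in the inflorescence meristem. In 3 others the signs were also opposite but 1 of the differences was under 1, namely Si011432m.g (5.83 and -0.46), Si011450m.g (4.85 and -0.89) and Si030858m.g (-0.07 and 5.59). The difference between the tissues was not tested, since each sample has 1 column. For Si004648m.g and Si019730m.g the shoot change rests on the V3 bulk shoot, the sample in which both were highest.

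In the R against V3 bulk shoots, 94.2% of the genes past the size rule were higher at R. The part of scaling in this cannot be told apart, since the share was 51.4% after median-ratio rescaling and 97.1% after rescaling to equal sums. Both rescalings also changed levels against the fixed pseudocount and FPKM minimum, and so more than the relative scale of the samples. Equal sums raised all values, while the median ratio lowered those of R and raised those of V3. Panicle tissue within the R bulk shoot may be a source of the 89 genes higher both as deposited and after median-ratio rescaling. A mixture lies below its source, and 64 of the 89 (71.9%) were at a higher FPKM in a panicle sample than in the R bulk shoot. In the pre-anthesis panicle alone 59 were. Of all 11470 genes at FPKM 5 in either bulk shoot, 35.6% lay above the R bulk shoot in a panicle sample, so such a position is common and does not by itself point to panicle tissue. For those 64, panicle tissue and expression in the shoot itself at stage R cannot be told apart, as the labels do not say what the bulk shoot contained. For the other 25, which were at or below the R bulk shoot in both panicle samples (16 of them by at least 4-fold both as deposited and after median-ratio rescaling), panicle tissue like these samples is argued against as the whole source.

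Genes of the pre-anthesis panicle were present in the R bulk shoot, most of them within 3-fold of their median fraction of the panicle level. Of 94 genes at FPKM 20 or more in that panicle and at least 10-fold above each V3 or V5 bulk shoot and leaf sample, 93 were at FPKM 1 or more in the R bulk shoot, with a median of 20.4% of the panicle level (quartiles 14.4% and 30.9%). Within 3-fold of that median lay 89.4% of them, against 53.2% around the corresponding median in the inflorescence meristem and 26.6% in the coleoptile. Only 50 of the 94 reached FPKM 1 in the coleoptile and 86 in the meristem, so low values there can widen the scatter. The bound of 3-fold each way is loose. Admixed tissue like the pre-anthesis panicle stays a hypothesis. A stricter definition tried first left only 3 genes (66.7% in the R shoot, 100% in the meristem) and was given up for that reason, and 5 other definitions with 32 to 155 genes gave 87.5% to 93.5% in the R shoot and 49.1% to 61.9% in the meristem. Use of the 94 genes by the stem or leaves at stage R was not tested and stays open. Genes of the post-anthesis panicle were mostly absent from the R bulk shoot. These were 48 genes at FPKM 20 or more there and at least 10-fold above the same samples and the pre-anthesis panicle. Of them 8 reached FPKM 1 in the R bulk shoot, with a median of 0.147% of the panicle level. The hypothesis is therefore limited to tissue like the pre-anthesis panicle.

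Start offsets were more positive in genes with higher expression. Several annotated transcripts per gene are argued against as the cause, since rho was 0.330 in the 3781 genes with 1 transcript (95% bootstrap interval over genes 0.301 to 0.359). The number of reads behind each start may still contribute and cannot be told apart from expression, because rho was 0.203 in the 3289 genes at FPKM 1 or more in all samples and neither depth nor gene length was given. No biological explanation was tested.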

How the results depend on the processing

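The settings of the comparisons, their thresholds and most alternatives were chosen before the data were examined. Chosen after seeing the data were the mean of transcripts, leaving out the root sample or the R bulk shoot, offsets of genes with 1 transcript, the check of called genes in samples not used to call them and its rescaled form, and the definitions of panicle genes. Counts are those of tip against base, tip against lower section, tip against mid section, the meristems, vegetative meristem against shoot, the panicles, root against shoot, coleoptile against shoot, V5 against V3 and R against V3 shoots, in this order. With a pseudocount of 5 they were 156, 548, 476, 76, 521, 167, 2025, 288, 5 and 74. With an FPKM of at least 20 they were 210, 714, 619, 135, 699, 232, 2291, 378, 8 and 121. With a log2 difference of at least 1 they were 1564, 3400, 2916, 1810, 4546, 1288, 7728, 2137, 372 and 2771. A pseudocount of 0.1 gave 413 for the meristems. Stricter settings pass fewer genes by construction and looser ones more. Total counts stayed within 1.5 times of the reported ones under both rescalings, no FPKM minimum and the mean of transcripts. At FPKM 5 the median sample had 9026 expressed genes. Over genes with a mean FPKM of at least 1 the median similarity was 0.786, with the root still farthest from the other 12. Sample-specific genes numbered 2255 with tau on linear FPKM, 1840 at FPKM 1, 329 at FPKM 20 and 249 without the root sample, against 896 without the R bulk shoot. Constant genes numbered 147 after rescaling, 33 and 3 at a mean FPKM of at least 1 and 50, 37 by a highest to lowest ratio under 2, 61 without the root sample and 45 without the R bulk shoot. Negative offsets made up 66.3% in genes with 1 transcript. Tests of explanations were revised after their values were seen. Scaling was first judged on the median-ratio share alone (51.4%, which would have favoured it), the 2 groups of R shoot genes replaced a single share (71.9%) that lay under a bound of 75, and a difference of 18 nt between median offsets was dropped because it restated the pattern. Beyond the size of the thresholds, the cause of these shifts was not tested. No paired analysis was possible because each sample has 1 merged column, and leaving out replicates was not run for the same reason. Also not run were the gene list medians, for want of gene names, and start-proximal introns, for want of a genome. Depth is unknown, so its limits could not be set.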

Other observations

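The inflorescence meristem and the V5 bulk shoot, a pair outside the report's comparisons and looked at only after the data had been seen, differed by the size rule in 835 genes higher and 856 lower in the meristem. Median-ratio rescaling moved the meristem by -0.34 against the shoot and gave 416 higher and 1037 lower. In leaf 3, the 835 genes had median log2(FPKM + 1) values of 0.95 in the lower section, 1.16 in the mid section, 0.58 in the base and 0.77 in the tip. The 856 genes had medians of 5.37, 5.25, 5.49 and 5.72 in the same parts. With rescaled values the medians of the same 835 and 856 genes were 0.99, 1.20, 0.78 and 0.91 for the first set, and 5.46, 5.32, 6.02 and 6.04 for the second.

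Start offsets were listed for 29 genes that reached an FPKM of 1 in no sample, the highest of them at 0.972.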
